A study of Mus musculus with 9 samples.

How the data were processed

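Liver RNA of male C57BL/6J mice, an inbred laboratory strain, was measured on 9 single-colour Agilent arrays carrying probes for mRNAs and long noncoding RNAs. Per the labels, each array held Cy3-labelled RNA of 1 pooled liver sample from 4 mice, and each of the 3 groups had 3 such pools, so that 36 mice contributed. A pooled value is an average over its mice, and the spread between the 3 pools of a group is smaller than the spread between single mice would be. Replicate pools of a group were separate samples per the labels, and no 2 arrays held identical values.

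Per the file headers, the authors scanned the arrays and extracted spot signals with Agilent Feature Extraction 11.5.1.1, whereas the submitters' processing notes give version 10.7; the reason for the difference is not given in the sources used here. The deposited processed signal is an intensity on a linear scale, already background-subtracted and spatially detrended within each array per the file headers. The deposited table of the whole series holds log2 values. Set against the scanner values, each of its columns equalled the log2 processed signal less 1 constant per array that puts the array's 75th percentile at 0, within 0.01 for at least 99.97% of the probes of every array. Its scale, centring and direction were therefore known, its column medians lay between -2.39 and -2.16, and it brought no independent normalization. The header's build field names mm9. The only reference table used here gives gene names and positions on GRCm38.p6, so it served for names and neighbouring genes, and no coordinates are printed.

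Each array had 175906 spots outside the controls. Spots with an outlier mark were removed (73 to 192 per array), and no spot was saturated. Between 53.0% and 63.5% of spots per array were well above background in the extraction software's own test, and the median local background was 20.0 to 24.5 intensity units against an upper-quartile signal of 191 to 279. Log2 processed signals were averaged over the spots of a probe and each array's 75th percentile was subtracted, which gave 97836 probes. A probe counted as above background on an array when a share of at least 0.5 of its spots were, and was tested when this held on at least 3 of 9 arrays. That left 62091 probes, of which 55 lacked a value on some array, and 62036 were tested. All levels below are log2 signal relative to the array's 75th percentile. Levels of different probes are not comparable with each other. Arrays give no counts, and the number of arrays limits the precision.

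Most probes have no gene name in the files. The 39027 probes of Agilent's catalogue and the 28773 NONCODE probes come with an identifier alone, and no table pairing these identifiers with genes was used here. Names were taken from RefSeq accessions in the probe identifiers for 4658 probes, from RIKEN clone identifiers for 1212, and from a gene name inside the identifier for 19. After filtering, 2711 named genes were tested, 470 coding and 2241 noncoding. A probe named through a RIKEN clone may measure a transcript of the locus other than its main mRNA. Where a gene had several tested probes, the brightest stood for it.

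The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 9 arrays with 1 mean per group, and Benjamini-Hochberg adjustment was applied over the tested probes of each contrast at 0.05. Standard errors (SE) are those of this fit, with 6 residual and 3.75 prior degrees of freedom. A single probe tested alone by permutation of 3 arrays against 3 could not reach a two-sided p under 0.1, so the adjusted p-values rest on limma's pooling of the spread across probes. Groups of 3 arrays lie apart by chance for 10% of unchanged probes. Where every array of 1 group was not well above background, the change is given as a bound, with the bright group's mean set against, per array of the dim group, the higher of the lowest signal well above background and the probe's own.

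Gene lists were tested with camera (preset correlation 0.01), with all named genes as background and a minimum of 5 tested members, and also with a correlation estimated from the data and with fry, which tests whether a list's members move, on balance, one way. Of 33 lists fixed before the data were examined, 1 reached 5 named and tested members, 9 had 1 or 2, and 23 had none. None of the 12 genes that were to be reported whatever their values had a named probe. Noncoding transcripts that overlap a coding gene of a list, or lie within 50 kb of one, were tested as neighbour lists instead, of which 10 reached 5 members. The neighbour lists and 4 groups of named noncoding RNAs were added after the probe identifiers and some values had been seen. List p-values were adjusted within each contrast over lists of the same kind: the 1 fixed list, the 10 neighbour lists, or the 4 groups. The adjusted p of the fixed list is therefore its unadjusted p. No adjustment was made over all lists of a contrast together. The rule for genes named in the text, also fixed beforehand, took for each contrast the called genes with the largest changes whose groups did not overlap (up to 6 coding and 3 noncoding each way, or the 3 smallest p each way where none passed) and up to 3 members of each list. The results of 2 genes that this rule names are not reported here. Unnamed probes and other genes that are singled out were chosen after their values were seen.

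Slides were read from the scan identifiers in the file headers, which the labels do not state, and all slide values rest on this reading. It gives 3 slides, each scanned on its own: the 3 controls and 1 high fat diet pool on slide 1, 2 high fat diet and 2 metformin pools on slide 2, and 1 metformin pool on slide 3. Slide was therefore partly tied to group. Alternatives to the main settings, chosen beforehand, were normexp background correction with an offset of 50, quantile normalization, the percentile over probes above background on all arrays, the authors' table, other filters, eBayes with trend and robust options, slide as a fixed or random block, arrays of a single slide, replicate number as a block, only the 2 groups compared, and each array left out. Array quality weights, and counts of changes of at least 2-fold with each array left out, were added after the data were seen. The mean spot signal that normexp was planned on was not among the columns used here, so the median spot signal and median local background were used. Covariances, correlations and shares of signs between contrasts that share arrays were set beside values simulated without effects. The fit was tested on 10 simulated data sets with 200 of 62036 probes changed between high fat diet and control: it called 32.0% of changes of 1 on the log2 scale and 88.5% of changes of 2, with a mean of 5.9 false calls. Figures were drawn with matplotlib 3.10.9.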

Results

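Transcripts in the livers of male C57BL/6J mice were measured in 3 groups of 3 pools, each pool from 4 mice aged 20 weeks. Control mice ate standard chow for 17 weeks, with no gavage recorded. The high fat diet group ate chow with 45% of its energy as fat for 17 weeks, with saline by gavage in the last 5 weeks. The metformin group ate the same diet and received metformin, a drug that lowers blood glucose in type 2 diabetes, at 3 mg/kg per day by gavage in the last 5 weeks. Of the 62036 probes tested, 33025 came from noncoding transcript collections or RIKEN clones and 29011 from a catalogue without gene names in the files. Between 53162 and 63707 of the 97836 probes per array were above background.

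Correlations across all tested probes, which are not independent replicates, ran from 0.973 to 0.990 within the controls, from 0.982 to 0.984 within the high fat diet pools and from 0.986 to 0.988 within the metformin pools. High fat diet replicates 1 and 2 each reached 0.9856 with a pool of another group, above any correlation within their own. The first principal component held 31.5% of the variance and separated the 3 controls from the other 6 pools. Control replicate 1 lay apart from the other controls, with 600 tested probes more than 2 above the median of the other arrays on the log2 scale, against 19 to 80 on each other array. The groups were only partly crossed with the 3 slides read from the file headers: slide 1 held the controls and high fat diet replicate 1, slide 2 the other high fat diet pools and metformin replicates 1 and 2, and slide 3 metformin replicate 3.

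**Figure D1:**
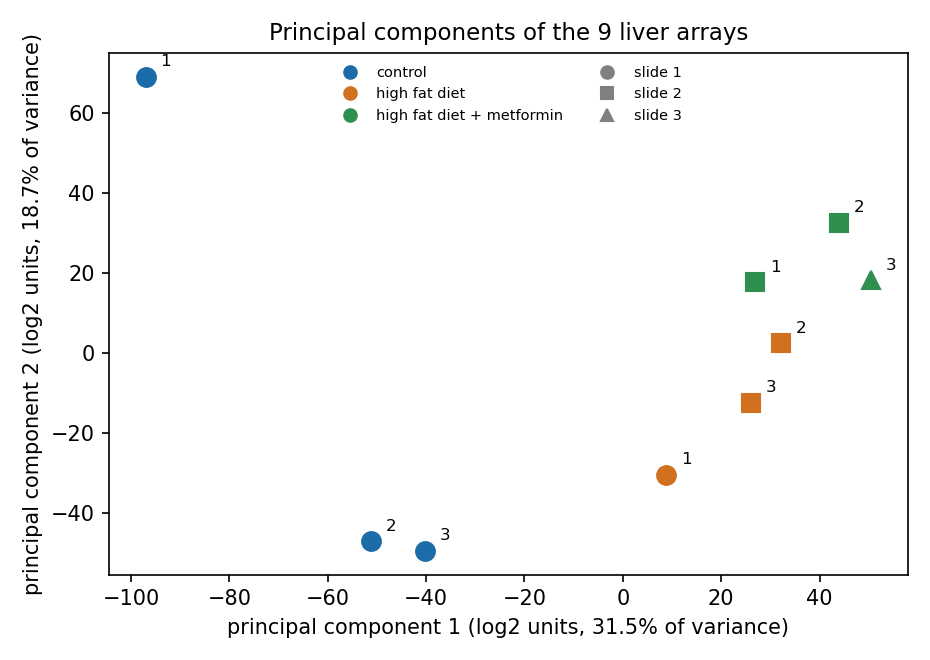
Position of the 9 arrays on the first and second principal components (31.5% and 18.7% of the variance) of log2 signal over the tested probes; each point is 1 pool, by group and slide. The controls lie between -97 and -40.2 on the first component, the high fat diet pools between 8.8 and 32.2, and the metformin pools between 26.9 and 50.5.

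The first comparison asked which liver transcripts a high fat diet alters, and it includes the saline gavage of that group. Gm32128, a predicted noncoding RNA near the phosphatase subunit gene Ppp2r5a, rose to -2.51 ± 0.10 (SD, n = 3) in the high fat diet pools and was not above background in any control. That was an increase of at least 2.40-fold (limma adjusted p = 0.0472), with all 3 pools above all 3 controls. Gm38830, a predicted noncoding RNA near Rnf103 and Chmp3, fell from -2.88 ± 0.05 (SD, n = 3) to below background in all 3 high fat diet pools, at least 2.54-fold (adjusted p = 0.029). Both transcripts lie near background, and both bounds rest on a lenient floor and may be too high. Among unnamed probes, A_55_P2033600 was at least 4.46-fold higher (adjusted p = 0.0244), and A_55_P2058550 fell by 3.47 (SE 0.35, adjusted p = 0.0224). The imprinted noncoding RNAs Rian and Meg3, which lie in 1 cluster, were lower in every high fat diet pool than in every control but did not pass the test over all probes. Rian was at -1.26 ± 0.75 (SD, n = 3) in the controls and below background in all 3 high fat diet pools. Its change of -2.25 (SE 0.41, limma adjusted p = 0.109) is therefore uncertain in size. Meg3 was at -1.94 ± 0.11 (SD, n = 3) against -0.44 ± 0.54 (SE 0.29, adjusted p = 0.122).

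Limma called 0 of the members of the metabolic, immune and clock lists with a named probe between high fat diet and control. Few genes stand behind this, since 9 lists had 1 or 2 tested members and most had none. The coding genes below were read through RIKEN clone probes, which may not measure the main mRNA. The clock repressor Cry2 was lower by less than 1 on the log2 scale (-0.51, SE 0.15, adjusted p = 0.227), and the chemokine Cxcl14 was higher (0.99, SE 0.36, adjusted p = 0.314), each with groups that did not overlap. The desaturase Fads2 (-0.03), the complex I subunits Ndufab1 (0.20) and Ndufa6 (-0.09), Sod1 (0.09), Mx2 (0.19, a transcribed pseudogene in the reference used) and Igf1 (-0.18) had adjusted p-values of 0.687 to 0.979. In all, 28 probes passed, 8 higher and 20 lower, of which Gm32128 and Gm38830 had gene names. The majority of lower probes did not hold without control replicate 1 (6 higher, 5 lower), and with probes above background on all 9 arrays it was 10 higher and 12 lower. At an unadjusted p under 0.05 there were 7493 probes, 3029 higher and 4464 lower, where 3102 would be expected by chance, and the groups did not overlap for 15.4% of probes against 10% by chance. Of the 1438 probes with an unadjusted p under 0.05 and a change of at least 2-fold, 81.3% were lower, and 72% without control replicate 1.

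Single arrays decided which diet calls passed. With slide as a block, where high fat diet replicate 1 alone stands against the controls, A_55_P2058550 was at -3.25, close to its value above. In that fit 2 probes passed, neither among the 28, and 2985 had an unadjusted p under 0.05. The count was 11, 3 and 2 without control replicates 1, 2 and 3, and 17 without metformin replicate 2. It was 296 without high fat diet replicate 1, and 0 without replicate 2 (5721 at an unadjusted p under 0.05) or replicate 3 (6240). Gm32128 passed under 5 and Gm38830 under 8 of 21 alternatives, each with the same sign in all 21.

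The second comparison asked what metformin changes in mice kept on the high fat diet. All 4 probes that passed were unnamed, and all 4 are given here, chosen after their values were seen. Clone E030029E13 was at -0.06 ± 0.39 (SD, n = 3) in the metformin pools against -3.87 ± 0.60, a rise of 3.80 (SE 0.33, adjusted p = 0.0154), whose size is uncertain because 1 of 3 high fat diet pools was above background. Clone F430001A17 rose by 1.85 (SE 0.15, adjusted p = 0.0154) to 2.41 ± 0.08 (SD, n = 3). NONMMUT057558 rose by 1.64 (SE 0.16, adjusted p = 0.0374) to 3.14 ± 0.12 (SD, n = 3), where the controls were at 1.15 ± 0.10. A_55_P2071646 fell by 1.39 (SE 0.14, adjusted p = 0.0374) to -0.58 ± 0.08 (SD, n = 3), while the controls were at -0.21 ± 0.10. In each of the 4 the groups did not overlap.

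Limma called 0 named genes between metformin and high fat diet. Gm35393, a predicted noncoding RNA near Adam23, was lower by the most among the 6 named genes with the smallest p, 3 each way (-3.99, SE 0.91, adjusted p = 0.502), with groups that did not overlap, and Tmcc3 was at -0.64 (SE 0.15, adjusted p = 0.514). The smallest p-values belonged to the predicted noncoding RNAs Gm39094 (0.96, SE 0.18, adjusted p = 0.396) and Gm39398 (0.72, SE 0.14, adjusted p = 0.396). Gm39443, which overlaps the protein kinase A subunit gene Prkar1a, was at least 3.61-fold higher (adjusted p = 0.483), and Mir1a-1hg, the host transcript of a muscle microRNA, was at least 2.13-fold lower (adjusted p = 0.483). Igf1 differed by -0.45 (SE 0.26, adjusted p = 0.814). Fads2 (0.26), Fmo2 (0.61), Ndufab1 (-0.23) and Cxcl14 (-0.46) had adjusted p-values of 0.735 to 0.864. Across all probes 4122 had an unadjusted p under 0.05 where 3102 would be expected by chance, and the groups did not overlap for 16.2% against 10% by chance.

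With slide as a block the changes were 1.71 for clone F430001A17, 1.48 for NONMMUT057558 and -1.47 for A_55_P2071646, close to those above, while Gm35393 was at -2.53. Leaving out 1 array moved Gm35393 between -5.08 (without high fat diet replicate 3) and -3.15 (without metformin replicate 3), with -3.37 and -3.52 without high fat diet replicates 1 and 2 and -4.64 without metformin replicate 2. In the fit with slide as a block, which compares 2 pools with 2 on slide 2, limma called 0 probes, with 2621 at an unadjusted p under 0.05. The count was 4 without high fat diet replicate 3, 3 without control replicate 1 and 2 without control replicate 3. It was 0 without control replicate 2, high fat diet replicates 1 or 2, or any metformin pool, where 2839 to 4004 probes had an unadjusted p under 0.05.

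The third comparison set the metformin pools against the controls, and so took diet and drug together. Chaserr, a noncoding RNA that overlaps Chd2 and is known to restrain it, rose to -2.33 ± 0.30 (SD, n = 3) and was not above background in any control, at least 2.95-fold (adjusted p = 0.0238). The histone reader Zmynd8 rose by 1.59 (SE 0.28, adjusted p = 0.0459) from -2.75 ± 0.08 to -1.16 ± 0.38 (SD, n = 3). Its probe comes from a RIKEN clone and may not read its main mRNA. Gm39094, near Wdr11, rose by 1.43 (SE 0.18, adjusted p = 0.0193), and Gm32128 was at least 2.59-fold higher (adjusted p = 0.0192). Gm35393, near Adam23, fell by 5.15 (SE 0.91, adjusted p = 0.0472), with pools that differed widely from each other. Speer4cos fell by 2.05 (SE 0.36, adjusted p = 0.0467), with control replicate 1 at -0.78 against -2.11 and -2.21 in the other controls, and was at -1.59 without that array (adjusted p = 0.026, range 0.00641 to 1 over its alternatives); 1 of 3 metformin pools was above background. The noncoding 1700040G22Rik was at least 7.89-fold lower (adjusted p = 0.0285). In each of these 7 the groups did not overlap.

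Of the 339 probes that passed between metformin and control, 147 were higher and 192 lower, and 22 had gene names. The majority turned with normexp background correction (302 higher, 272 lower) and with quantile normalization (241 higher, 221 lower). Another called pair, Gm38830 (at least 2.42-fold lower, adjusted p = 0.0152) and Speer5-ps1 (-1.71, adjusted p = 0.0152, control replicate 1 at -0.78 against -1.14 and -1.36), was chosen after the values were seen. Rian (-2.01, SE 0.41, adjusted p = 0.059), above background in 1 of 3 metformin pools, and Meg3 (-1.08, SE 0.29, adjusted p = 0.102) did not pass. Igf1 (-0.63, SE 0.26, adjusted p = 0.234) and Cry2 (-0.40, SE 0.15, adjusted p = 0.197) did not pass either. At an unadjusted p under 0.05 there were 11831 probes, 5368 higher and 6463 lower, against 3102 expected by chance, and the groups did not overlap for 24.9% against 10% by chance. Of 2004 probes with an unadjusted p under 0.05 and a change of at least 2-fold, 79.8% were lower, and 73.5% without control replicate 1.

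These groups share no slide, and the number of calls moved with each array. With slide as a block limma called 0 probes between metformin and control, with 2644 at an unadjusted p under 0.05. In that fit Gm39094 (1.41) and Speer4cos (-1.98) kept most of their change, and Zmynd8 (0.74) and Gm35393 (-2.45) did not. Adjusted p-values of the 7 named transcripts above were 0.632 to 1 there and 0.00232 to 1 over all alternatives. Chaserr passed under 13 of 20 alternatives, Zmynd8 under 11 and Speer4cos under 8, with the same sign in all 20. Without control replicates 1, 2 and 3 the count was 2711, 7 and 89. Without high fat diet replicates 1, 2 and 3, which enter only through the pooled spread, it was 678, 187 and 584, and without metformin replicates 1, 2 and 3 it was 77, 48 and 2.

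**Figure D2:**
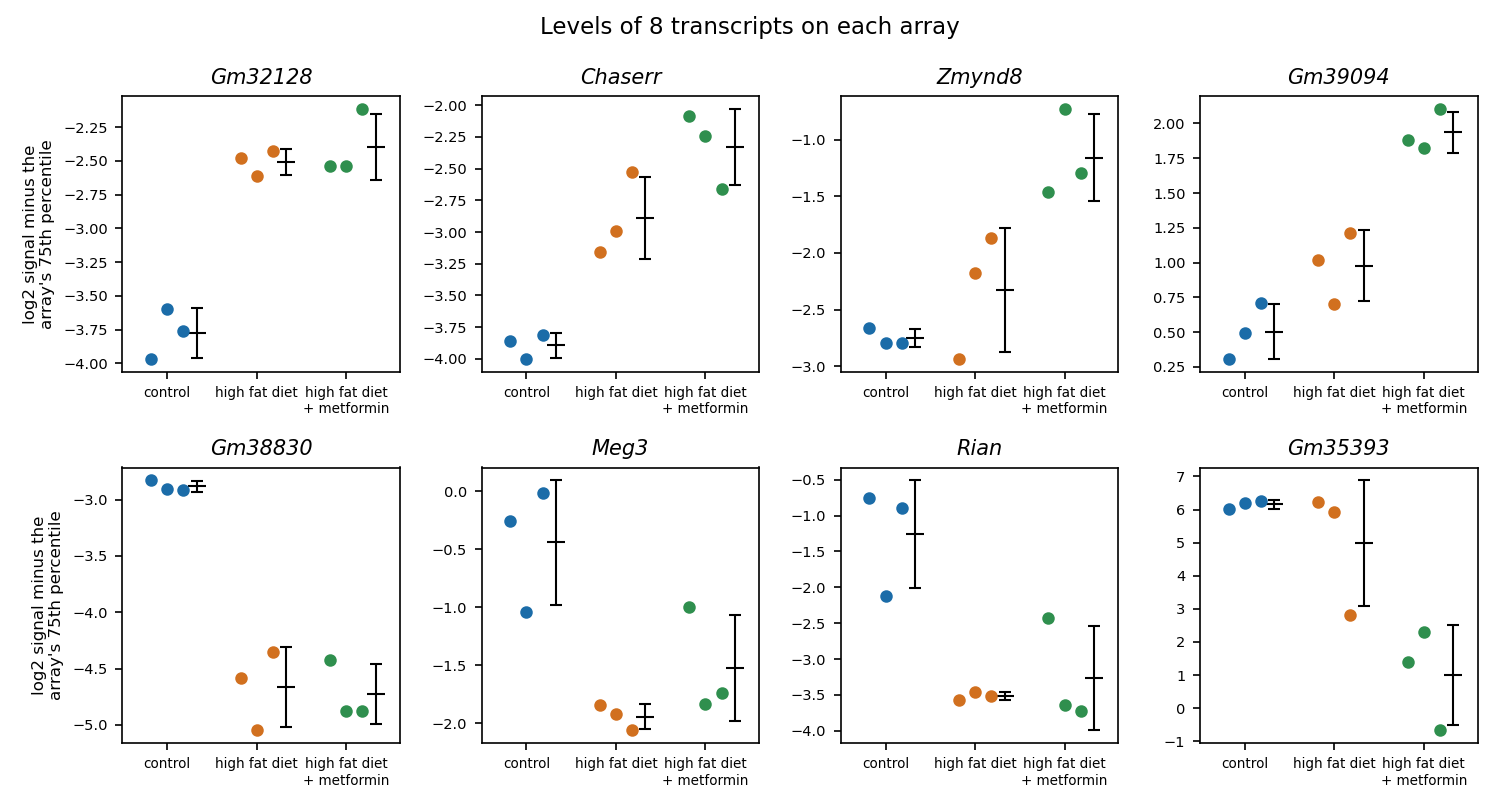
Log2 signal relative to each array's 75th percentile for 8 noncoding or coding transcripts in control, high fat diet and metformin livers; points are pools, and bars give mean ± SD (n = 3). Chaserr, Zmynd8 and Gm39094 have their highest means in the metformin pools, Meg3 and Rian in the controls, and Gm35393 ranges from -0.67 to 6.26 over the 9 pools.

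Whether metformin moved the diet's transcripts back toward control was asked across all probes. Of the 28 probes that passed between high fat diet and control, 21 had the opposite sign between metformin and high fat diet, all 21 with a smaller change, and limma called 0 of the 28 there. Because both contrasts use the same high fat diet pools, opposite signs arise without any effect. Among the 7493 probes with an unadjusted p under 0.05 for diet, 60.2% had the opposite sign, against 87.5% in data simulated without effects. The covariance of both contrasts was -0.0159 against -0.0353 simulated, an excess of 0.0194 (jackknife SE 0.0124). The simulation holds no diet effects, and these alone would lower the opposite share, so the shares do not decide on a reversal. The covariance showed no reversal across transcripts beyond what the shared pools give. A slide shift, which the layout would add to both contrasts and the simulation lacks, could hide one. The excess covariance was 0.00509 with normexp background correction, which also shrank log2 changes, -0.00159 with slide as a block, and 0.0122 to 0.0281 under the other alternatives.

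Both diet groups differed from the controls in overlapping ways. Of the 28 probes called for high fat diet with saline, 21 were also called between metformin and control with the same sign, Gm32128 and Gm38830 among them. The contrasts share the 3 controls, and across probes they correlated at 0.772 against 0.50 in data simulated without effects. The simulation holds no slide shift, which the layout would add to both contrasts, and with slide as a block 0 of the 28 and 0 of the 339 calls remained (2985 and 2644 at an unadjusted p under 0.05 in limma). Among the 3 groups together, 77 probes differed (limma's F test), with 9505 at an unadjusted p under 0.05; the count was 0 with slide as a block, with 2835.

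As a list, 13 named long noncoding RNAs fixed beforehand did not pass camera in the 3 comparisons. Between high fat diet and control their mean was -0.28 and their median 0.06, so these differed in sign, with 7 higher and 6 lower (camera adjusted p = 0.76; 0.766 with an estimated correlation). Rian and Meg3 passed when adjusted over the list alone, and 0 members passed over all probes. Between metformin and high fat diet the mean was -0.06 and 8 of 13 were lower (adjusted p = 0.246; 0.281 with an estimated correlation). Airn, an imprinted noncoding RNA, had the smallest p (-0.69, SE 0.22, adjusted p = 0.626 over all probes), while its other probe gave -0.06, and 0 members passed over the list alone. Between metformin and control the mean was -0.34 and 9 of 13 were lower (adjusted p = 0.195; 0.234 with an estimated correlation), which passed with fry (adjusted p = 0.0382) and without control replicate 1 (0.0411), with a range of 0.0382 to 0.497 over the alternatives, and with Rian and Meg3 again the 2 that passed when adjusted over the list alone.

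Noncoding transcripts beside genes of 10 liver pathways and cell types, chosen after the identifiers were seen, did not shift as lists either. Their lowest camera adjusted p was 0.867 between high fat diet and control, 0.327 between metformin and high fat diet and 0.888 between metformin and control. Neighbours of hepatocyte marker genes came nearest, with 6 of 6 higher and a mean of 0.20 between metformin and high fat diet (adjusted p = 0.327; 0.497 with an estimated correlation). Neighbours of fatty acid and triglyceride synthesis genes had a mean of -0.24 with diet (6 of 8 lower, adjusted p = 0.867; 0.988 with an estimated correlation) and 0.12 with metformin on the diet (5 of 8 higher, adjusted p = 0.389; 0.497 with an estimated correlation). Gssos2 overlaps Gss and counts here because the acetate-activating enzyme gene Acss2 lies within 50 kb. It was at -0.78 with diet (SE 0.23, adjusted p = 0.229) and at 0.63 with metformin on the diet (SE 0.23, adjusted p = 0.676). Between metformin and control, Gm31535 beside the antioxidant gene Srxn1 was at 0.59 (SE 0.13, adjusted p = 0.0736), while its other probe gave 0.11. Gm34315 beside Amacr (0.59, SE 0.15, adjusted p = 0.089) and Gm39813 beside Gpd2 (0.59, SE 0.15, adjusted p = 0.0887) did not pass either. Gpd2, the mitochondrial glycerophosphate dehydrogenase, is a reported target of metformin, and its own mRNA has no named probe here. The other list results, which include fatty acid oxidation, lipid droplets, bile acids, complex I, oxidative stress, the circadian clock, macrophages and exocrine pancreas, had adjusted p-values of 0.327 to 0.985.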

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

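Array quality weights were chosen after the data were seen, and the other alternatives before. Counts below are for high fat diet against control, metformin against high fat diet, metformin against control, and all 3 groups, in that order; with the settings of the report they were 28, 4, 339 and 77. Normexp background correction gave 60 (24 higher, 36 lower), 7 (6 higher, 1 lower), 574 (302 higher, 272 lower) and 200, and kept 16, 4 and 185 of the calls of the 3 contrasts. Without a filter the counts were 12, 2, 96 and 35, which tests more probes. With probes above background on all 9 arrays, metformin against control gave 638, 151 of them among the 339. Trend and robust options gave 62, 9, 1208 and 439. Slide as a fixed block gave 2, 0, 0 and 0, with 2621 to 2985 probes at an unadjusted p under 0.05. Slide as a random block gave 202, 4, 8243 and 4689 and kept all 28, 4 and 339 calls of the 3 contrasts, with a consensus correlation of -0.168. A negative correlation makes that fit take contrasts between slides as more precise. Its counts therefore do not show that the calls outlast an adjustment for slide. Limma called 0 within slide 1 (high fat diet against control, 2522 at an unadjusted p under 0.05), which holds 1 high fat diet array, and 0 within slide 2 (metformin against high fat diet, 2 arrays each, 3630); such small groups say little on stability. Replicate number as a block gave 0, 0, 79 and 8, with 7932 and 4223 at an unadjusted p under 0.05 in the first pair. Replicate numbers did not pair the arrays: same-number residual correlations ran from -0.0939 to 0.128. A fit of only the 2 groups gave 0 (5884 at an unadjusted p under 0.05) for metformin against high fat diet and 602 for metformin against control. Array quality weights gave 60, 7, 6761 and 2137, and kept all 28, 4 and 339 calls. An unadjusted p under 0.05 with a change of at least 2-fold gave 1438, 326, 2004 and 2281. With each array left out, counts ranged from 0 to 296, 0 to 4, 2 to 2711 and 0 to 347; a group left with 2 arrays borrows the spread of the others. For these settings the cause was not tested, except where fewer or more probes or arrays entered. Quantile normalization, the percentile over probes above background and the authors' table stayed within 1.5 times of every count, though quantile normalization gave 241 higher and 221 lower for metformin against control. The fixed gene list had 0 calls except in metformin against control, with 1 under fry (adjusted p = 0.0382) and 1 without control replicate 1 (adjusted p = 0.0411), and its left-out range there was 0 to 1; its adjusted p there ran from 0.0382 to 0.497 over the alternatives. The excess covariance of diet and metformin effects moved from 0.0194 to 0.00509 with normexp and to -0.00159 with the slide block. Normexp with its offset also shrank log2 changes, such as the diet mean of the imprinted noncoding RNAs from -0.80 to -0.39. Its covariance is therefore on a smaller scale than the main one. Named genes and singled-out probes never reversed a call: 1796 of 1866, 1960 of 2000 and 1765 of 1902 values in the 3 contrasts stayed on their side of the threshold, 68, 36 and 91 became weaker, and 2, 4 and 46 stronger. Most of these values belong to genes that were not called and stayed so, and the calls themselves were less stable. For diet, Gm32128 passed under 5 of 21 alternatives and A_55_P2058550 under 15 of 22. For metformin on the diet, A_55_P2071646 passed under 8 of 22 and clone F430001A17 under 12 of 22. Between metformin and control, Speer4cos passed under 8 of 20 and Gm32128 under 16 of 20. Low signal limits these arrays, since only 53.0% to 63.5% of spots per array were well above background.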

Other observations

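The tests of explanations, the splits of the arrays, the 4 groups of noncoding RNAs (tested in 3 contrasts each) and the array quality weights in this part were chosen after the result was seen, while the counts with each array left out were planned. Imprinted noncoding RNAs were lower on the high fat diet than in the controls, by a mean of -0.80 with 5 of 6 members lower (camera adjusted p = 0.0408; 0.22 with an estimated correlation, 0.0197 with fry). Rian (-2.25, SE 0.41, below background in all 3 high fat diet pools) and Meg3 (-1.50, SE 0.29) gave most of it. Kcnq1ot1 was at -0.79 (SE 0.33), Igf2os at -0.49 (SE 0.22) and Peg13 at -0.14 (SE 0.29), and Airn was higher at 0.39 (SE 0.22). In the metformin pools the mean was -0.76 against control, again with 5 of 6 lower (adjusted p = 0.0394; 0.217 with an estimated correlation), and between metformin and high fat diet it was 0.04 (adjusted p = 0.987). Adjusted p for diet ran from 0.00303 to 0.22 over the alternatives and the other set tests. With slide as a block the diet mean was -0.74 (adjusted p = 0.0288), which rests on 1 high fat diet array. The diet call was lost without control replicate 3 (mean -0.69, adjusted p = 0.211), high fat diet replicate 1 (-0.82, 0.114) or 2 (-0.82, 0.0551), or metformin replicate 2 (-0.80, 0.0565), with means near the full one. Against control, the metformin call was lost with slide as a block (-0.53, adjusted p = 0.123) and with only the 2 groups (0.0686). It was also lost without control replicate 3 (0.224), high fat diet replicate 2 (0.0556) or 3 (0.05), or metformin replicate 3 (0.152). Of the 6, 4 also belong to the list of named long noncoding RNAs fixed beforehand. The unadjusted camera p was 0.0102 for diet and 0.00985 for metformin against control. Adjusted p-values of the 4 groups cover these groups alone and not the other lists tested, so they are lenient.

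Small nucleolar RNA host genes, whose introns encode RNAs that guide ribosomal RNA modification, were lower with metformin on the high fat diet, by a mean of -0.37 with 6 of 7 lower (adjusted p = 0.00872; 0.0821 with an estimated correlation, 0.153 with fry). Snhg18 (-0.80, SE 0.33), Snhg16 (-0.54, SE 0.27), Snhg7 (-0.53, SE 0.26), Snhg3 (-0.39, SE 0.24), Snhg5 (-0.24, SE 0.22) and Snhg8 (-0.19, SE 0.28) were lower, none past the test alone. With slide as a block the mean was -0.48 (adjusted p = 0.000524) and within slide 2 the adjusted p was 0.000394. The call was lost without high fat diet replicate 3 (0.171) and with probes above background on all 9 arrays (0.0733), and adjusted p ran from 0.000394 to 0.171 over the alternatives. Between high fat diet and control the mean was 0.03 (adjusted p = 0.743), and between metformin and control -0.33 (adjusted p = 0.249), where it passed without control replicate 1 (0.0242), with array quality weights (0.0457) and with slide as a block (0.015). Of the 7, 3 also belong to the list fixed beforehand. MicroRNA host genes (6 tested) had adjusted p-values of 0.189, 0.086 and 0.886 for diet, metformin on the diet, and metformin against control. For metformin on the diet they passed with normexp (0.0257), without a filter (0.0277), without high fat diet replicate 1 (0.0292) and without metformin replicate 1 (0.0254), with a range up to 0.80 over the alternatives. The 53 opposite-strand transcripts had 0.957, 0.987 and 0.886.

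Meg3 and Rian are noncoding RNAs of 1 imprinted cluster, both transcribed from the maternal chromosome, and 1 shared control may set both. Their deviations from the group means over the 9 pools went together (r = 0.948, exact permutation p = 0.0972, one-sided over 216 permutations within groups; rho = 0.917, exact permutation p = 0.106). Without the 2 pools farthest out, r was 0.859. Across the tested probes, 0.0355% had a higher correlation with Meg3 than Rian had. The test did not reach 0.05. Rian was below background in the high fat diet pools and above it in only 1 of 3 metformin pools, so these correlations rest largely on the other pools. A shared control stays open.

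Other splits of the arrays were counted for each comparison. High fat diet against control called 28 probes and the highest other of its 10 splits 0; metformin against high fat diet called 4 against 1, and metformin against control 339 against 1. In each of the 3, only 1 split, the real one, gave as many, and 10 splits are too few for a share under 0.05. For all 3 groups, 1 of 100 splits, the real one, gave 77 probes or more, and the highest other gave 9. Chance alone was therefore unlikely to give 77. The count was 0 without metformin replicate 3, with 7122 at an unadjusted p under 0.05. Slide is partly tied to group, and these splits do not separate them.

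Control replicate 1 stood apart, with correlations of 0.9635 to 0.9747 to the other arrays and an array weight of 0.238 against 0.701 to 1.76. Scatter between spots was excluded as the source: its duplicate spots differed by an SD of 0.157, inside the 0.149 to 0.169 of the others. Probes of the vomeronasal receptors, pheromone receptor genes in many copies, were 2.34 higher there (median of 6, random lists 0.27). Those of the Speer family were 1.40 higher (median of 3), where the highest other array reached 1.04. Sequence of multi-copy families, as genomic DNA would bring, could be a source. Part of the rise was shared by the controls. Among the tested probes of both families, Speer4cos, Speer5-ps1 and Vmn1r-ps79 were also higher in control replicates 2 and 3 than in every high fat diet or metformin pool. Vmn2r29 was so in control replicate 3 only. Olfactory receptor probes, not seen among the most deviating, were 0.30 higher (median of 7), above 74.2% of 10000 random lists of matched signal, which decides neither way, and 4 of these 7 probes, like 4 of the 6 vomeronasal ones, were too near background to be tested. The test replaced one over all 16 probes, above 99.97% of lists, because the other families had been seen among the most deviating probes; genomic DNA, another cell source and a difference between mice stay open.

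Most calls lay between metformin and control, groups on different slides, so slide may add to them. For 602 probes called from those 6 arrays alone, the mean signed shift of 1.52 held 0.742 within slide 1, 0.462 between slides inside the high fat diet group and 0.315 within slide 2. The share between slides was 30.4%, but a single array, high fat diet replicate 1, gives the slide 1 value, so slide and group cannot be told apart; a first test on the 339 calls, which were chosen with the high fat diet arrays in the fit, gave 2.13%. Diet and metformin shifts that add in one direction could also raise the count: the steps within slide 1 and within slide 2, which share no array, correlated at -0.012 across 62036 probes (rho -0.0141), and the bound for this test was widened after its value, so it stays open. The count was 2711, 7 and 89 without control replicates 1, 2 and 3, 678, 187 and 584 without high fat diet replicates 1, 2 and 3, and 77, 48 and 2 without metformin replicates 1, 2 and 3.

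Gm35393 was near its full level in some pools and far below it in others: in percent of the control mean it was at 89.9, 103 and 108 in the controls, at 106, 85.7 and 9.8 in the high fat diet pools, and at 3.65, 6.9 and 0.882 in the metformin pools. Slide alone did not account for this, since the 4 arrays of slide 2 ranged over 4.55 on the log2 scale against 0.261 in the controls. Only high fat diet replicate 2 was near full level among them. Metformin as the whole cause was not excluded: the high fat diet pools ranged over 3.43, but only through replicate 3 (both ranges replaced a comparison of single pools). A wrong label of that pool would undo its range. It lay with its group on clone F430001A17 (0.70 against 2.35 to 2.50 in the metformin pools) and on A_55_P2071646 (0.69 against -0.66 to -0.50). Both probes were called with this label in the fit, so they cannot test it. A candidate explanation is pools that mix mice with and without the transcript. There, 1 allele of the 8 in a pool would give 12.5% and 1 mouse 25%. The 9.8% of high fat diet replicate 3 lies near the first step, and the metformin pools lie under it. All mice were of 1 inbred strain, in which alleles are not expected to differ between mice. RNA amounts per mouse are not known and no single mouse was measured, so the levels cannot decide this.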
